A study of Mus musculus with 10 samples.

How the data were processed

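Total RNA from cultured mouse cells was labelled with Cy3 and hybridised to 10 Agilent arrays, 1 sample per array. Per the labels, 4 arrays held induced embryonic Sertoli-like cells (ieSCs) made from female tail tip fibroblasts (TTFs), 4 held ieSCs made from mouse embryonic fibroblasts (MEFs), and 2 held MEFs as the control. The arrays carry 5 names, 2 arrays for each: names 1 and 2 of each kind of ieSC, and the MEFs. In what follows an array is called by its name and a letter, such as 2b. The labels do not say whether 2 arrays with a shared name came from separate cultures, and nothing places names 1 and 2 in separate animals. The p-values then measure the spread between these arrays and names, part of which may be technical. Groups were taken from the source names in the labels.

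The deposited table holds log2 array intensity for 62976 features on the 10 arrays, from 0.288 to 19.02. The submitters' processing notes name limma, with no version, and the values show the rest of what is known. The sorted values of the 10 deposited log2 columns differ by at most 0.0379 above the 40th percentile, which is how quantile-normalized columns look, and the column medians lie between 5.759 and 5.782. The log base was taken as 2 from this range. Background correction is not given in the sources used here. Quantile normalization gives every array the same distribution, so a change in the total amount of mRNA per cell cannot be seen. The deposited table has no detection flags, so there is no measured line between a gene that is present and a gene that is not. Levels below about 5.0 (the 40th percentile lay between 4.988 and 5.023) belong to the dim end of an array, and a difference against such a level depends on where the array's floor lies. For such a gene the log2 difference is a measured one on the deposited scale and not a ratio of transcript amounts.

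Gene names came from the platform annotation of the features, with 31465 features naming 1 gene symbol, 0 naming several and 31511 naming none. Symbols were updated through the RefSeq gene table (assembly GRCm38.p6, used only for names and gene order), in which the accessions of 29050 features matched, and 3282 features received a newer symbol. Unnamed features were tested but not reported by gene. A feature was kept if it was above the 40th percentile of its array on at least 2 arrays, which left 42617 features, 25200 of them named. Each gene was represented by its kept feature with the highest mean over all 10 arrays, giving 16650 genes. Repeat spots of a probe could not be recognised, since probe names are not used here, so repeats were not averaged. Of the genes tested, 4839 had more than 1 kept feature, and for named genes whose features differed widely the range over features is given. The position of a feature within its gene is not used here, so transcripts of a transgene and of the cell's own gene are not separated.

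Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with a mean for each of the 3 groups fitted to all 10 arrays and the shared name of 2 arrays as a random block (duplicateCorrelation, consensus correlation 0.606). The moderated test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 16650 genes, with a threshold of 0.05. The fit had 7 residual degrees of freedom, of which 2 lie between names, and a prior of 2.21. All 8 ieSC arrays were compared with MEF as the mean of the 2 ieSC groups, each ieSC group was compared with MEF, and the ieSC groups were compared with each other. Values are log2 differences ± standard error (SE) from this fit, and group levels are means ± SD over 2 MEF or 4 ieSC arrays. The array number limits the precision: the median SE was 0.174 for ieSC against MEF and 0.156 between the ieSC groups. Both ieSC groups were set against the same 2 MEF arrays, so the overlap of those comparisons was also simulated 20 times with unchanged groups against shared controls. The control arrays were not divided, because each part would hold 1 array.

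Before the data were examined, 30 gene lists (661 genes), the rule for naming genes, the tests and the alternatives were fixed. Of the list genes, 633 had a named feature and 581 were tested. The sex-linked list was used as a check of the labels and not tested as a list. The other 29 lists were tested with cameraPR on the moderated statistic, with a preset inter-gene correlation of 0.01 and adjustment over the 29 lists, and again with a correlation estimated from the residuals. Fry, which tests whether a list changes without setting it against other genes, was run with the same block, and its p-values were not adjusted. Lists are said to pass or not by cameraPR. The genes named for ieSC against MEF were the 5 transgene factors, the 8 largest rises and the 8 largest falls past the threshold in which every ieSC array lay on the same side of both MEF arrays, and up to 4 members per list by smallest p. For the comparison of the ieSC groups the 8 largest each way without overlap were taken, and for each ieSC group against MEF the 5 largest each way, with predicted genes left out. Other list members are named where a group is described, and these were picked after their values were seen.

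The fit was tested on simulated data for the 16650 genes with the estimated correlation and 200 changed genes per comparison. For ieSC against MEF it recovered 13.2% of genes changed 1.5-fold, 60.3% of those changed 2-fold and 84.8% of those changed 4-fold, and 4.72% of its calls were false. Between the ieSC groups it recovered 28.2%, 78.7% and 91.2%, and 15 of 145 calls (10.3%) were false, above the intended share. The correlation put in was 0.606 and the one found was 0.51. Alternatives were no name block, the arrays of each name averaged, the submitters' code series as a block, repeated quantile normalization, median and 75th percentile centring, other filters on dim features, the mean of a gene's features, a trended robust variance, only the groups compared, an added 2-fold threshold, an estimated inter-gene correlation, a label number as block, and arrays or names left out in turn. With the arrays of each name averaged the MEFs are 1 value, which is assumed to vary like the ieSC names. Figures were drawn with matplotlib.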

Results

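Gene expression was measured on 10 arrays of cultured mouse cells: 4 of induced embryonic Sertoli-like cells (ieSCs) from female tail tip fibroblasts (TTFs), 4 of ieSCs from mouse embryonic fibroblasts (MEFs), and 2 of MEFs. Sertoli cells are the somatic cells of the testis tubules that surround and support the germ cells. Per the labels, the ieSCs carried doxycycline-inducible transgenes for the 5 factors Nr5a1, Wt1, Dmrt1, Gata4 and Sox9 and had grown without doxycycline for 2 weeks, and the MEFs were cultured for 2 weeks as well. The series set the ieSCs beside unconverted MEFs to ask how their expression differs from that of fibroblasts. Across all features, arrays with the same name correlated at 0.9896 to 0.9966, arrays of the same ieSC group with different names at 0.9878 to 0.9896, ieSCs of the different origins at 0.9675 to 0.9754, and MEF with ieSC arrays at 0.926 to 0.9408. The median absolute log2 difference between arrays of a name was 0.0849 to 0.12, and between names 1 and 2 it was 0.166 in MEF-derived and 0.175 in TTF-derived ieSCs.

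The ieSCs differed from MEFs by higher embryonic Sertoli markers and lower imprinted, anterior and central Hox, macrophage, peritubular, Wnt and TGF-beta genes, the 7 lists that passed with the preset and with an estimated correlation. Among the transgene factors, Wt1, which encodes a zinc finger protein of gonad and kidney development, rose by 5.60 ± 0.27 on the log2 scale, a fold change of 48.5, to levels of 17.12 in MEF-derived and 17.06 in TTF-derived ieSCs. The other 4 factors fell: Sox9 by -3.46 ± 0.17, Gata4 by -1.90 ± 0.32, Nr5a1 by -0.68 ± 0.13 and Dmrt1 by -0.50 ± 0.16. The adjusted p of Dmrt1 was 0.024, and it was 0.0563 with the arrays of each name averaged and 0.0742 without the second MEF array. In TTF-derived ieSCs alone Dmrt1 did not pass against MEFs (adjusted p = 0.108). In MEFs Sox9 stood at 11.18, and in ieSCs at 7.96 and 7.48. Gata4 stood at 7.585 in MEFs and at 5.769 and 5.611 in ieSCs, not far above the filter level. Nr5a1 stood at 7.906 in MEFs and at 7.2 and 7.256 in ieSCs. Dmrt1 lay at 8.176 and 8.374 on the MEF arrays and at 7.53 to 8.067 on the ieSC arrays. As a list of 5, the factors did not differ from other genes (adjusted p = 0.519).

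The embryonic Sertoli markers rose as a list, with 16 of 33 measured members higher and 7 lower (median log2 difference 0.62, cameraPR adjusted p = 0.000253, and 4.16e-05 with an estimated correlation). Dhh, a hedgehog ligand secreted by Sertoli cells, rose by 7.23 ± 0.14 and Tesc, a calcium-binding protein, by 7.38 ± 0.20. Nt5e rose by 5.46 ± 0.24 and Gatm, an enzyme of creatine synthesis, by 3.68 ± 0.20. The ligands Gdnf and Kitl, which act on germ cells, rose by 3.60 and 3.40, and Sox8 rose by 2.32. Emx2, Tcf21 and Lhx9, transcription factors of the early gonad, fell by 4.45, 2.85 and 2.18. Amh, the anti-Mullerian hormone of fetal Sertoli cells, was below the filter, with levels of 4.24 in MEF, 4.74 in MEF-derived and 4.10 in TTF-derived ieSCs. Of the 15 mature Sertoli markers, 7 rose and 5 fell, and the list did not pass (adjusted p = 0.673). Rhox5, an X-linked homeobox gene of Sertoli cells, rose by 4.81 ± 0.51, Ctsl by 1.57 ± 0.17, and Trf, which encodes transferrin, by 3.42. Wnt5a fell by 7.55 ± 0.23, and Rhox8 by 1.57 ± 0.13 on the feature taken while its features ranged from -1.57 to 0.166.

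Fibroblast and mesenchymal markers fell in 22 of 34 members and rose in 0 (median -2.98, adjusted p = 4.01e-09, but adjusted p = 0.0588 with an estimated correlation). Thy1, a surface protein used as a fibroblast marker, fell by -12.3 ± 0.28 from a MEF level of 17.24, and Col1a2, a chain of type I collagen, by -11.02 ± 0.51 from 18.7. Fap fell by -9.19 ± 0.24 and the receptor gene Pdgfra by -4.76 ± 0.22. The transcription factors Twist1, Prrx1 and Snai2 fell by 8.47, 6.48 and 1.57. Several members did not pass: Col3a1 differed by 0.14 ± 0.14, Vim by 0.15 ± 0.16 and Sparc by -0.19 ± 0.16. Peritubular and smooth muscle markers fell in 10 of 13 members and rose in 1 (adjusted p = 9.56e-06, and 0.0481 with an estimated correlation). The myosin light chain gene Myl9 fell by -10.2 ± 0.32 and Actg2, a smooth muscle actin, by -7.69 ± 0.36.

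**Figure D1:**
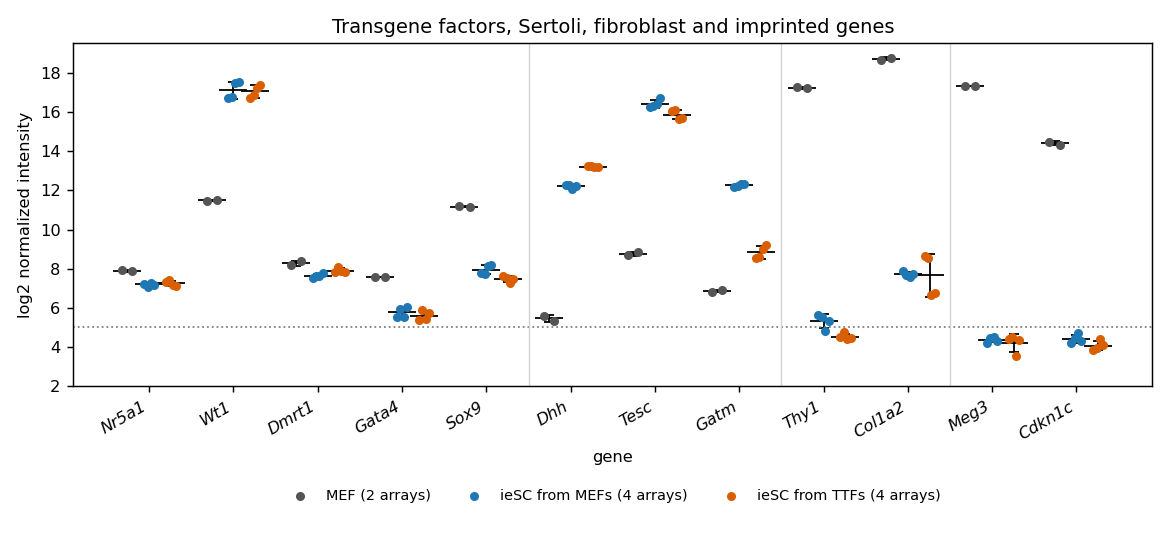
Log2 normalized intensity (vertical axis) of 12 genes on each of the 10 arrays, with black marks for the group mean ± SD and a dotted line at the highest filter level, 5.023. Wt1 is above MEF in every ieSC array while Sox9 is below, Dhh, Tesc and Gatm are higher, and Thy1, Col1a2, Meg3 and Cdkn1c are lower.

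Imprinted growth genes, which are expressed from a single parental copy, gave the smallest list p of this comparison: 15 of 16 fell and 0 rose (median -6.33, adjusted p = 1.98e-28, and 1.22e-32 with an estimated correlation). Meg3, a noncoding RNA, fell by -13.03 ± 0.37 on the feature taken, and its 3 features ranged from -13.0 to -7.02. Mirg, from the same cluster, fell by -8.71 ± 0.16, the cell cycle inhibitor Cdkn1c by -10.15 ± 0.25 and Ndn by -5.46 ± 0.16. H19 and Igf2 fell by 9.67 and 4.58. Peg10 did not pass, at -0.33. Of the anterior and central Hox genes, which pattern the body axis, 19 of 24 fell and 1 rose (median -2.67, adjusted p = 1.09e-08, and 2.72e-07 with an estimated correlation). Hoxc6 fell by -8.30 ± 0.41, Hoxc9 by -7.59 ± 0.40, Hoxb2 by -7.19 ± 0.24 and Hoxb9 by -6.01 ± 0.29, while Hoxa9 rose by 1.97. Of 10 posterior Hox genes, 4 rose and 5 fell (adjusted p = 0.848). Hoxd11 rose by 1.62 ± 0.23 and Hoxa10 by 1.05 ± 0.12, and Hoxd12 fell by -4.14 ± 0.52 and Hoxc10 by -3.63 ± 0.25.

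Mesothelial and coelomic epithelium markers, of the lining of the body cavity from which the gonad surface forms, rose in 11 and fell in 5 of 17 members (median 2.61, adjusted p = 0.000158). Their adjusted p was 0.0729 with an estimated correlation and 0.0906 with the arrays of each name averaged. Aldh1a1, a retinaldehyde dehydrogenase, rose by 5.65 ± 0.13, Podxl by 5.97 ± 0.32, mesothelin (Msln) by 4.81 ± 0.18 and Upk3b by 4.53 ± 0.19. Epithelial and junction genes rose in 11 and fell in 2 of 29 members (adjusted p = 0.0046, but 0.169 with an estimated correlation and 0.0829 with averaged arrays). The tight junction gene Cldn3 rose by 6.81 ± 0.38, F11r by 5.18 ± 0.31, and desmoplakin (Dsp) by 5.41 ± 0.20, with its 11 features between 0.973 and 5.43. Basement membrane genes did not pass as a list, with 9 of 21 higher and 6 lower (adjusted p = 0.62). The collagen IV genes Col4a6 and Col4a5 rose by 4.31 ± 0.14 and 2.17 ± 0.11, and Nid1 and Lamb1 fell by 8.52 ± 0.29 and 5.10 ± 0.26. The features of Col4a6 ranged from 2.53 to 4.31 and those of Nid1 from -8.52 to -4.07.

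Hypoxia and glycolysis genes rose in 21 and fell in 2 of 26 members (median 1.52, adjusted p = 9.45e-08, but 0.0636 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, rose by 5.61 ± 0.34, Ero1a by 3.69 ± 0.15, Bnip3 by 2.27 ± 0.12 and Vegfa by 2.11 ± 0.11, and Adm fell by 3.84. Wnt signalling genes fell in 17 and rose in 6 of 32 members (adjusted p = 2.72e-06, and 0.000217 with an estimated correlation). The members that fell include secreted antagonists as well as ligands: Sfrp2 fell by 11.56 ± 0.38, Dkk3 by 11.22 ± 0.31, Rspo3 by 11.07 ± 0.36 and Wnt5a by 7.55 ± 0.23. Axin2 and Tcf7, which respond to Wnt signals, rose by 2.69 and 2.68. TGF-beta and activin signalling genes fell in 13 and rose in 6 of 27 members (adjusted p = 0.00195, and 0.000737 with an estimated correlation). Grem1, a BMP antagonist, fell by -9.54 ± 0.52, Bmp4 by -8.715 ± 0.54 and Tgfbi by -7.89 ± 0.17. Cholesterol synthesis genes fell in 13 and rose in 0 of 20 members (adjusted p = 0.0111, but 0.582 with an estimated correlation and 0.098 with averaged arrays). Fdps, Cyp51, Mvk and Mvd differed by -2.14 ± 0.23, -2.13 ± 0.24, -1.88 ± 0.15 and -1.59 ± 0.16, all of them falls.

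Markers of other cell types were measured too. Macrophage markers were lower in ieSCs in 17 of 19 members and higher in 1 (median -5.52, adjusted p = 1.40e-22, and 2.97e-17 with an estimated correlation). C1qa, a complement component of macrophages, fell by -8.30 ± 0.25 from a MEF level of 12.31, Laptm5 by -7.24 ± 0.19, Ctss by -7.25 ± 0.25 and Fcer1g by -6.08 ± 0.18, while Cd53 rose by 1.18. That rise came from MEF-derived ieSCs (10.07, against 7.75 in MEFs), and TTF-derived ieSCs, at 7.80, did not pass against MEFs for Cd53 (adjusted p = 0.94). Single inflammatory genes went both ways: Tnf fell by -4.87 ± 0.097 (features from -6.06 to -4.87) and Il1b by -2.65 ± 0.11, and Lcn2 rose by 3.90 ± 0.13. Over the inflammatory list 6 of 29 rose and 11 fell (adjusted p = 0.128), and over the interferon response list 6 of 34 rose and 19 fell (adjusted p = 0.059). Bst2 and Ifih1, genes induced by interferon, fell by -3.26 ± 0.23 and -5.11 ± 0.53.

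Granulosa and ovarian markers fell in 8 and rose in 3 of 12 members (adjusted p = 0.0223, but 0.101 with an estimated correlation and 0.0593 without MEF-derived name 1). Irx3 fell by 8.24 ± 0.26, whereas Rspo1, an ovarian Wnt agonist, rose by 3.27 ± 0.18. Of the 13 Leydig and steroidogenic genes, 1 rose and 4 fell (adjusted p = 0.5). Tspo rose by 2.78 ± 0.10, and the steroid enzymes Hsd3b1 and Cyp11a1 fell by 6.03 ± 0.24 and 5.83 ± 0.51. Chondrocyte genes fell in 12 and rose in 2 of 20 members (adjusted p = 0.00207, but 0.058 with an estimated correlation), with Col2a1 lower by -8.49 ± 0.42 and Prg4 higher by 4.35 ± 0.22 (features from 1.99 to 4.35). Cardiac and skeletal muscle genes fell in 11 and rose in 3 of 21 members (adjusted p = 0.0302, but 0.328 with an estimated correlation and 0.0692 without TTF-derived name 2). Tbx5 and Hand2, transcription factors of heart and limb, fell by 6.34 ± 0.41 and 5.25 ± 0.25. Podocyte and kidney genes fell in 8 and rose in 4 of 16 members (adjusted p = 0.0892), and that p was 0.0206 and 0.0307 without TTF-derived array 1a or 1b. Six2 fell by 7.62 ± 0.36 on the feature taken, with features from -7.62 to -0.929, and Osr1 fell by 6.98 ± 0.54.

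The endothelial, osteoblast, adipocyte, germ cell and p53 lists did not pass. Of 10 endothelial markers, 4 rose and 2 fell (adjusted p = 0.54), with Esam, a junction protein, up by 6.64 ± 0.31 and the receptor gene Eng down by -3.60 ± 0.28. Of 11 osteoblast genes, 2 rose and 4 fell (adjusted p = 0.578), and Spp1 rose by 1.63 ± 0.24, with levels of 14.49 in MEFs, 17.4 in MEF-derived and 14.84 in TTF-derived ieSCs, where it did not pass (adjusted p = 0.325). Of 10 adipocyte genes, 2 rose and 4 fell (adjusted p = 0.431), and the transcription factor gene Cebpa fell by 5.08 ± 0.47. Germ cell and pluripotency markers rose in 1 and fell in 2 of 16 members (adjusted p = 0.883), and Kit, the largest of these falls, differed by -1.47 ± 0.51 (adjusted p = 0.038). Kit is at the dim end in ieSCs (4.15 and 4.324), and its call was lost under 7 alternatives that each leave out 1 array, with limma adjusted p = 0.0595 and adjusted p = 0.0944 without the first or second MEF array. Of 22 p53 target and senescence genes, 4 rose and 6 fell (adjusted p = 0.578). Igfbp3 fell by 11.05 ± 0.50, and Gadd45a rose by 2.04 ± 0.13. The mean ieSC value of the cell cycle list covers levels that differed by origin: 30 of 42 members fell and 1 rose (median -0.85, adjusted p = 0.000387, but 0.466 with an estimated correlation). The median and the test of the mature Sertoli, basement membrane, germ cell and p53 lists differ in sign, and none of these 4 passed.

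Adjusted over the list alone, the counts of risen and fallen members were 1 and 22 for fibroblast, 9 and 7 for basement membrane, 1 and 11 for peritubular, 0 and 0 for germ cell, 1 and 18 for macrophage, 3 and 13 for chondrocyte, 2 and 5 for osteoblast, and 4 and 11 for cardiac and skeletal muscle genes. They were 1 and 31 for cell cycle, 9 and 13 for inflammatory, 7 and 15 for TGF-beta, and 21 and 3 for hypoxia genes. For the other 17 lists they equalled those over all genes.

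Among single genes, the largest rises in ieSCs were those of Prph, an intermediate filament gene of neurons (10.62 ± 0.22), Akr1c18, which inactivates progesterone (10.12 ± 0.61), the homeobox gene Tlx2 (9.64 ± 0.22) and Chil1 (8.33 ± 0.70). Dmkn, Cst12, Krt76 and Dpp4 followed, with 7.999, 7.91, 7.502 and 7.44. The largest falls, besides Meg3 and Thy1, were those of the chemokine genes Cxcl14 (-12.73 ± 0.38) and Cxcl12 (-12.34 ± 0.61), the opioid precursor gene Penk (-12.67 ± 0.33), Smoc2 (-11.63 ± 0.66), Sfrp2 and Lrrc17 (-11.33 ± 0.54). The MEF level of Tlx2 (4.26), Cst12 (3.29) and Krt76 (4.44) and the ieSC levels of most of the fallen genes were at the dim end of the arrays. In all, limma called 8248 of 16650 genes (49.5%) at an adjusted p under 0.05, 4314 higher and 3934 lower in ieSCs, and the median over all genes was 0.085. Of the called genes, 4362 differed at least 2-fold. With the arrays of each name averaged 5493 genes were called.

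In the check of the labels, Xist, the RNA that coats the inactive X chromosome, stood at 9.34 in MEFs and at 4.02 in MEF-derived and 4.004 in TTF-derived ieSCs, a log2 difference of -5.33 ± 0.49 (adjusted p = 1.6e-05). Female cells with an inactive X chromosome express Xist, yet on the 4 arrays of ieSCs labelled as from female TTFs it stood at 3.77 to 4.35, below the filter level, which is not what that label predicts. The Y-linked gene Eif2s3y stood at 10.3 in MEFs and at 3.64 and 3.71 in the ieSC groups (-6.64 ± 0.39, adjusted p = 7.6e-07). On the 4 TTF-derived arrays Eif2s3y stood at 3.42 to 4.01, and a dim Y-linked gene is what the female label predicts. The Y-linked genes Kdm5d and Uty did not pass the filter, with MEF levels of 4.33 and 4.73, and Uty stood at 6.62 on MEF-derived array 2b and at 3.47 on array 2a of the same name.

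**Figure D2:**
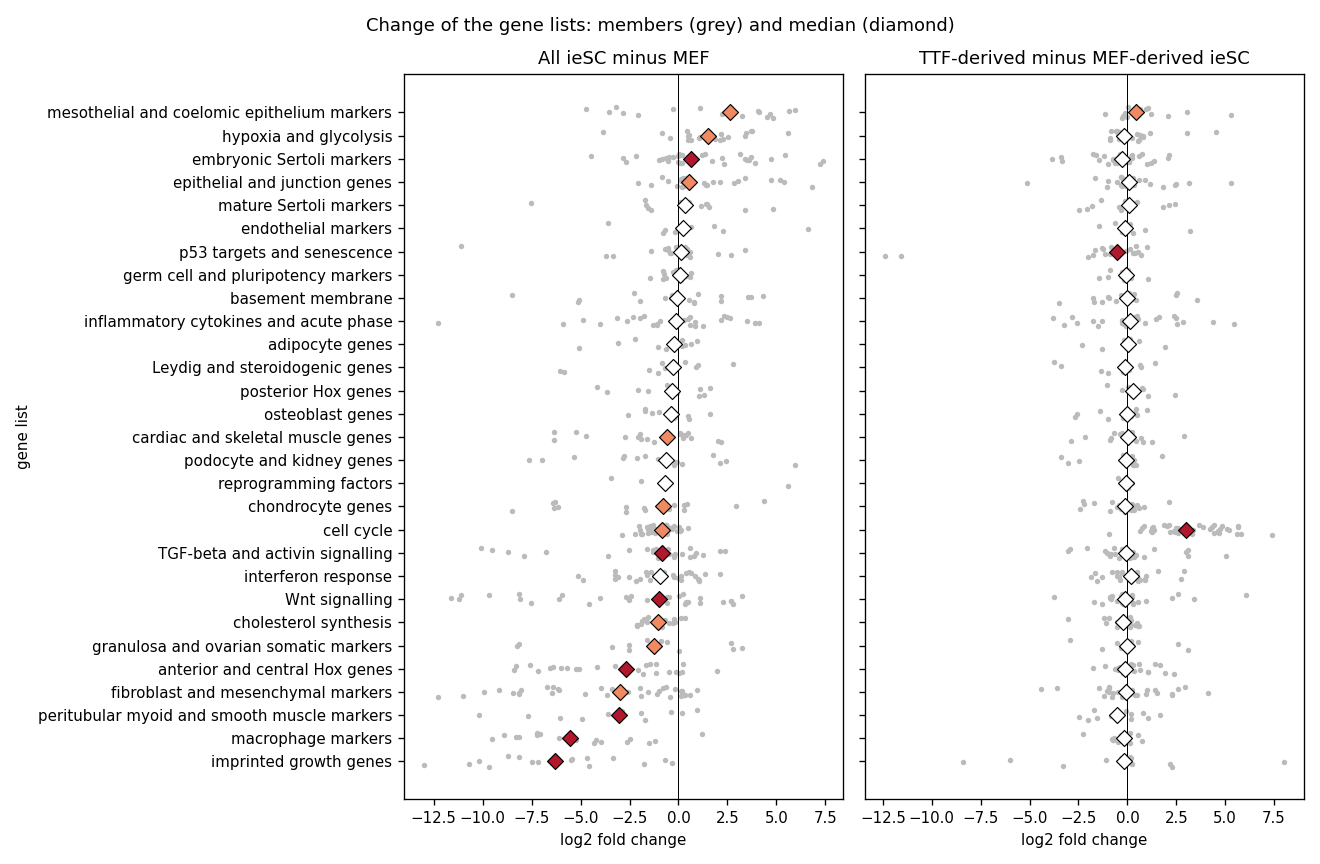
Log2 fold change (horizontal axes) of the members of 29 gene lists, as grey points, for all ieSCs minus MEF (left) and TTF-derived minus MEF-derived ieSCs (right). Diamonds are list medians, dark red where the list passed with the preset and with the estimated correlation, orange where it passed with the preset one alone, and white where it did not pass; imprinted growth genes lie lowest on the left (-6.33) and cell cycle genes highest on the right (2.98).

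Set against MEFs separately, both kinds of ieSC had the same leading falls. In MEF-derived ieSCs, which share the starting cell kind of the control, Meg3 fell by -12.94 ± 0.40, Penk by -12.83 ± 0.36, Cxcl14 by -12.78 ± 0.42, Cxcl12 by -12.2 ± 0.67 and Thy1 by -11.91 ± 0.31. In TTF-derived ieSCs the same 5 genes fell by 13.12, 12.5, 12.68, 12.47 and 12.7. All 5 had mean levels of 5.334 or lower in both kinds of ieSC, near the dim end, and both comparisons use the same MEF arrays. The sizes of these falls were thus largely set by the MEF levels. What the 2 kinds had in common is that all 5 genes were near the dim end. The largest rises in MEF-derived ieSCs were Akr1c18 (11.51 ± 0.67), Cst12 (10.1 ± 0.40), Serpinb9f (10.02 ± 0.25), Tlx2 (9.97 ± 0.24) and Serpinb9e (9.96 ± 0.30, with features from 6.77 to 9.96). In TTF-derived ieSCs they were Prph (11.77 ± 0.24), Chil1 (9.77 ± 0.76), Tlx2 (9.32 ± 0.24), Akr1c18 (8.73 ± 0.67) and Krt76 (8.11 ± 0.78). Serpinb9e, Serpinb9f and Serpinb9g are closely related protease inhibitor genes, and their features may share signal. Cell cycle genes fell in 39 of 42 members in MEF-derived ieSCs (median -2.22, adjusted p = 1.06e-19, and 0.0385 with an estimated correlation). In TTF-derived ieSCs 24 rose and 2 fell (median 0.795, adjusted p = 0.0256, but 0.621 with an estimated correlation). Embryonic Sertoli markers rose in 15 and fell in 6 of 33 members in MEF-derived ieSCs (adjusted p = 0.000107), and rose in 14 and fell in 7 in TTF-derived ieSCs (adjusted p = 0.00203).

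In MEF-derived ieSCs 8524 genes were called (4527 higher, 3997 lower), and in TTF-derived ieSCs 7512 (3872 higher, 3640 lower). Both comparisons called 2773 genes higher and 2685 lower, where independent lists of these sizes would share 1053 and 874. They called 286 genes in opposite directions, against 1919 for independent lists. The fold changes correlated across genes at r = 0.8548, and at a mean of 0.674 in simulations of unchanged groups against the same MEF arrays. The simulations shared 0 calls, but with no gene changed hardly any call was possible, so this does not gauge the number of shared calls. Same signs were found for 78.78% of genes, against 73.3% in the simulations. With no gene changed, the simulated correlation and share of signs are set by the array layout, whatever the size of the noise. They therefore do not gauge how much of the agreement came from the shared controls. The covariance was 2.791, against 0.0802 simulated, a difference of 2.711. Part of the excess may come from the shared control arrays. The starting TTFs were not analysed here, so the difference of TTF-derived ieSCs from MEFs holds both the conversion and the origin of the cells.

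The comparison of the ieSC groups asks whether cells of the same kind differ by the fibroblast they came from, and proliferation genes differed most. Each origin has 2 names, which nothing places in separate animals, and only the TTFs are labelled by sex. A difference by starting fibroblast therefore cannot be told apart from one of sex or of the particular cultures. Of 42 cell cycle genes, 40 were higher in TTF-derived ieSCs and 1, Ccne1, was lower (median 2.98, adjusted p = 2.05e-92, and 2.88e-07 with an estimated correlation). Mki67, a marker of proliferating cells, was higher by 7.39 ± 0.26, the topoisomerase gene Top2a by 5.83 ± 0.14, the cyclin gene Ccna2 by 5.58 ± 0.17, Ube2c by 5.68 ± 0.18 and the mitotic kinase gene Plk1 by 4.69 ± 0.12. In MEFs these genes were near the TTF-derived level: Top2a stood at 10.26 in MEF, 5.45 in MEF-derived and 11.28 in TTF-derived ieSCs. The cell cycle inhibitor genes Cdkn2a and Cdkn2b were lower in TTF-derived ieSCs by -12.37 ± 0.15 (features from -12.4 to -9.08) and -11.6 ± 0.21 (features from -11.6 to -8.74). Cdkn2a stood at 13.85 in MEF, 16.7 ± 0.11 (SD, n = 4) in MEF-derived and 4.33 ± 0.2 (SD, n = 4) in TTF-derived ieSCs, and Cdkn2b at 13.23, 15.33 and 3.73. The p53 target and senescence list, which holds both, was lower in 14 and higher in 2 of 22 members (median -0.52, adjusted p = 1.76e-12, and 0.000284 with an estimated correlation). Phlda3 and Gadd45a were lower by -1.30 ± 0.15 and -0.91 ± 0.12.

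**Figure D3:**
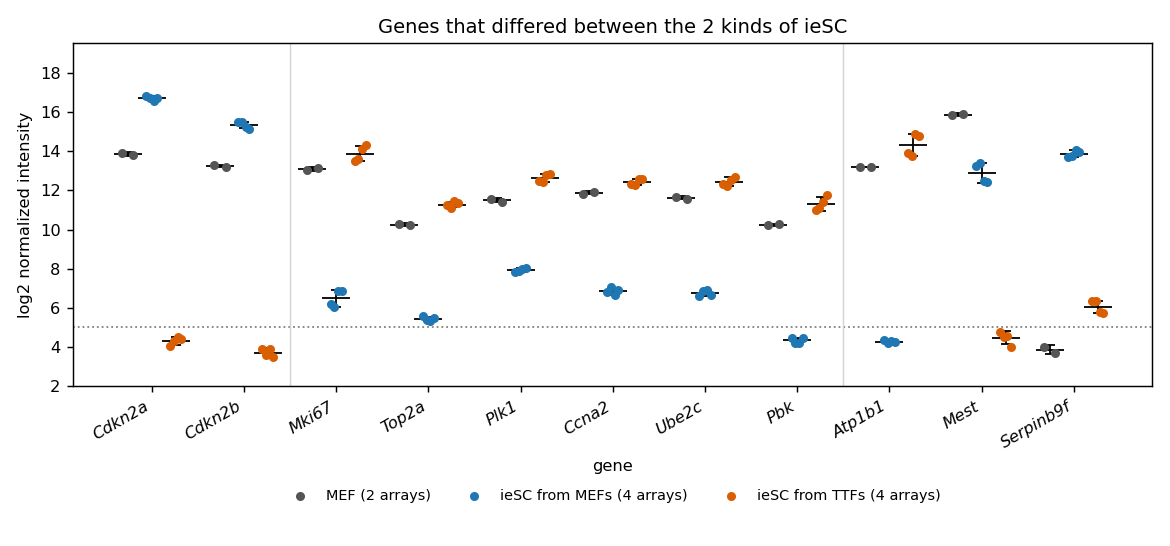
Log2 normalized intensity (vertical axis) of 11 genes on each of the 10 arrays, with black marks for the group mean ± SD and a dotted line at the highest filter level, 5.023. Cdkn2a and Cdkn2b are at the dim end in all TTF-derived arrays, and Mki67, Top2a, Plk1, Ccna2, Ube2c and Pbk are lowest in the MEF-derived arrays.

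Mesothelial and coelomic epithelium markers were higher in TTF-derived ieSCs in 6 and lower in 1 of 17 members (median 0.45, adjusted p = 0.0214, but 0.576 with an estimated correlation, 0.0525 with the stricter filter and 0.153 without TTF-derived name 1). Krt19 was higher by 5.29 ± 0.18 and Aldh1a2, which makes retinoic acid, by 3.06 ± 0.26. Both were bright in MEFs and lower in MEF-derived ieSCs. On the MEF arrays Krt19 stood at 10.41 and 10.42 and Aldh1a2 at 10.93 and 10.76, against at most 5.836 and 6.09 on the MEF-derived arrays. On the TTF-derived arrays Krt19 stood at 10.88 to 11.12 and Aldh1a2 at 8.368 to 9.079, below its MEF level. Of the embryonic Sertoli markers, 4 of 33 were higher and 10 lower, and the list did not pass (adjusted p = 0.337), though its p was 0.0275 without TTF-derived name 2. Gatm was lower in TTF-derived ieSCs by -3.41 ± 0.17, Erbb4 by -3.86 ± 0.27 and Cst9 by -3.35 ± 0.40, and Dhh was higher by 0.99 ± 0.13. Among the transgene factors only Sox9 passed, by -0.48 ± 0.15 (adjusted p = 0.035), and its call was lost under 9 alternatives, with adjusted p = 0.181 for averaged arrays and adjusted p = 0.0654 without MEF-derived array 2a. Nr5a1 and Gata4 differed by 0.06 ± 0.12 and -0.16 ± 0.28.

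Further differences lay within lists that did not pass. A higher value in TTF-derived ieSCs is not always a rise over MEFs. On the MEF arrays Ror2 stood at 12.84 and 12.75 and Peg3 at 11.18 and 11.19, above both ieSC groups. Of the imprinted genes, 3 of 16 were higher and 4 lower (adjusted p = 0.605): Mest was lower by -8.41 ± 0.31 (features from -8.66 to -3.59), Grb10 by -6.01 ± 0.25, and Peg3 was higher by 2.17 ± 0.16. Of epithelial genes, 6 of 29 were higher and 5 lower (adjusted p = 0.605), with the keratin gene Krt18 lower by -5.13 ± 0.37. Of 27 TGF-beta genes, 6 were higher and 11 lower (adjusted p = 0.605), with Tgfbi higher by 5.02 ± 0.15. Of 32 Wnt genes, 6 were higher and 5 lower (adjusted p = 0.93), with the receptor gene Ror2 higher by 6.08 ± 0.21. Of 26 hypoxia genes, 7 were higher and 5 lower (adjusted p = 0.93), with Adm higher by 4.55 ± 0.32 and Vegfa lower by -0.88 ± 0.094. Of 20 cholesterol genes, 1 was higher and 5 lower (adjusted p = 0.193, and 0.0135 without TTF-derived name 2), with Hsd17b7 lower by -3.04 ± 0.11. Of the Hox genes, 6 of 24 anterior or central ones were higher and 2 lower (adjusted p = 0.586), and 4 of 10 posterior ones were higher and 1 lower (adjusted p = 0.337), with Hoxa11 higher by 2.43 ± 0.17. Fibroblast markers were higher in 5 and lower in 8 of 34 members (adjusted p = 0.93), with Pdgfra higher by 2.26 ± 0.20 and Fbn1 lower by -4.41 ± 0.60. Fbn1 stood at 10.14 and 10.02 on the arrays of TTF-derived name 1 and at 7.463 and 7.602 on those of name 2, and was not called with averaged arrays (adjusted p = 0.057). Peritubular markers were higher in 2 and lower in 5 of 13 members (adjusted p = 0.605, and 0.0122 without MEF-derived name 2), with Acta2 lower by -2.001 ± 0.27.

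For macrophage markers 0 of 19 were higher and 3 lower (adjusted p = 0.657), and the lower members were Fcer1g, Cd53 (-2.27 ± 0.35) and Itgam (features from -0.787 to -0.0514). With the arrays of each name averaged, Cd53 and Itgam were not called (adjusted p = 0.0646 and 0.202). Interferon genes were higher in 6 and lower in 4 of 34 members (adjusted p = 0.657, and 0.0372 without MEF-derived name 1), and inflammatory genes in 7 and 7 of 29 (adjusted p = 0.93), with Ccl8 lower by -3.22 ± 0.22. Counts of higher and lower members were 4 and 5 of 15 for mature Sertoli markers, 4 and 5 of 21 for basement membrane, 2 and 4 of 13 for Leydig, 3 and 2 of 12 for granulosa, and 1 and 3 of 16 for germ cell genes. They were 1 and 0 of 10 for endothelial, 1 and 3 of 16 for podocyte, 2 and 6 of 20 for chondrocyte, 1 and 4 of 11 for osteoblast, 2 and 2 of 10 for adipocyte, and 4 and 4 of 21 for cardiac and skeletal muscle genes, with the lowest adjusted p of these lists at 0.595. The largest differences were those of Lamb1 among basement membrane (3.56), Hsd11b1 among Leydig (-3.73), Fst among granulosa (3.09), Tek among endothelial (3.19) and Foxc2 among podocyte genes (-3.37). Adjusted over the list alone, the counts were 0 and 0 for the factors, 3 and 7 for peritubular, 0 and 2 for macrophage, 7 and 1 for mesothelial, 41 and 1 for cell cycle, 4 and 14 for p53, 7 and 12 for TGF-beta, and 7 and 6 for hypoxia genes, and they equalled those over all genes for the other lists.

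The largest single differences in favour of TTF-derived ieSCs were those of Atp1b1, a sodium pump subunit gene (10.05 ± 0.25), Plagl1 (7.999 ± 0.35, with features from 0.0697 to 8.0), Gadd45g (7.63 ± 0.67), Mki67, Depp1 (6.98 ± 0.55), Pbk (6.97 ± 0.23), Maf (6.93 ± 0.29, with features from 1.62 to 6.93) and Fmo2 (6.93 ± 0.73). Of these, Atp1b1, Plagl1, Gadd45g, Mki67, Pbk and Maf were bright in MEFs too and far lower in MEF-derived ieSCs. On the MEF arrays Atp1b1 stood at 13.17 and 13.17, Plagl1 at 16.92 and 16.84, Gadd45g at 17 and 16.68, and Maf at 11.92 and 11.89. Depp1 and Fmo2 were dimmer in MEFs, at 6.494 and 6.122 and at 5.928 and 6.153, and were higher in TTF-derived ieSCs. The largest in favour of MEF-derived ieSCs, after Cdkn2a, Cdkn2b and Mest, were Serpinb9f (-7.83 ± 0.20), Serpinb9e (-7.80 ± 0.24, with features from -7.8 to -6.52), Serpinb9g (-7.47 ± 0.26), Evc2 (-7.35 ± 0.18, with features from -7.35 to -2.22) and Cemip (-7.23 ± 0.37, with features from -7.23 to -4.7). Mest, Evc2 and Cemip were bright in MEFs, at 15.83, 14.18 and 12.57 on the first MEF array, and far lower in TTF-derived ieSCs. In all, 5998 of 16650 genes (36%) were called, 2789 higher and 3209 lower in TTF-derived ieSCs, and 2241 of them differed at least 2-fold. With the arrays of each name averaged, 2421 genes were called.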

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

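The tests of failed features, of a segment reaching Mtap and of splits that keep names whole were chosen only after the result was seen.

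Between TTF-derived and MEF-derived ieSCs the changes against MEF differed, in a test of the difference itself, for 3 gene lists. The median difference was 2.98 for cell cycle genes, -0.518 for p53 targets and senescence genes and 0.449 for mesothelial markers, and the last was not called with an estimated correlation. Top2a differed by 5.828 ± 0.14 on the log2 scale. It fell by 4.81 in MEF-derived and rose by 1.02 in TTF-derived ieSCs. Only 3 splits of the ieSC arrays keep the arrays of each name together, too few for a share under 0.05. Among them 1, the real one, gave 5998 genes, and the highest other, names 1 against names 2, gave 28. In the other splits the difference by origin falls into the residual spread, which holds their counts low. The 28 is therefore no measure of the difference between names, and the split counts decide nothing.

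Cdkn2a and Cdkn2b differed between the same groups by -12.37 and -11.6, rising against MEF in MEF-derived ieSCs by 2.85 and 2.10 and falling in TTF-derived ieSCs by 9.52 and 9.503. Failed features are argued against, since all 4 features of the 2 genes were lower in every TTF-derived array than in every MEF-derived array. A loss of all copies that reaches the neighbouring gene Mtap is argued against as well, since the lowest TTF-derived level of Mtap lay 6.42 above the filter level. Mtap was lower than in MEF-derived ieSCs by -0.707 (limma adjusted p = 0.0015) but near its MEF level. It stood at 11.67 in MEFs, 12.23 in MEF-derived and 11.52 in TTF-derived ieSCs. A loss of 1 copy there stays open. On the other side a loss that takes the nearest gene, Dmrta1, cannot be told apart from none. Dmrta1 lay down to -2.14 from the filter level in TTF-derived ieSCs and was below it in MEFs too (3.82). The next measured gene there, Zfp352, stood at 12.12 in TTF-derived ieSCs, 11.06 in MEF-derived ieSCs and 11.06 in MEFs, so a loss of all copies reaching it was not seen in its RNA. A loss of the pair alone, or its silencing, in the TTF-derived cells may account for the values and stays open as a hypothesis, since the arrays measure RNA and the starting TTFs were not analysed here.

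The mean level of the posterior Hox list in TTF-derived array 2b lay far from the other 3 arrays of its group, with a gap of 0.911 of the group's range and above the critical value of Dixon's test at 4 arrays. It was 1 of 74 such tests, in which about 3.7 would pass by chance.

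Of 17417 features that pass the filter but have no gene name here, 4284 (24.6%) differed between ieSCs and MEFs, and 2775 differed between the ieSC groups.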

How the results depend on the processing

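All alternatives were fixed beforehand, and none reversed a result. With the arrays of each name averaged, the calls were 5493 for ieSC against MEF, 4763 for TTF-derived ieSCs against MEF, 2421 between the ieSC groups and 3508 shared by both comparisons with MEF, and this fit has only 2 residual degrees of freedom. In that averaged fit the MEFs are 1 value with no spread of its own. With at least a 2-fold difference required as well, the calls were 4362 for ieSC against MEF, 4839 for MEF-derived and 4293 for TTF-derived ieSCs against MEF, and 2241 between the ieSC groups. Without the name block they were 10545, 10751, 9838 and 8516. With an estimated inter-gene correlation, 7 lists passed for ieSC against MEF, in place of 16. With arrays or names left out, the lists past the threshold between the ieSC groups numbered 2 to 5, the 5 without TTF-derived name 2 and the 2 without TTF-derived name 1. Leaving out single arrays gave 7329 to 8058 calls for ieSC against MEF, where a lone MEF array is assumed to vary like the other groups. Leaving out both arrays of an ieSC name gave more calls for ieSC against MEF, 8607 to 9167, than the 8248 with all arrays. The MEFs have 1 name, so no spread between names was measured for them. Median centring gave 4659 higher and 3670 lower calls for ieSC against MEF, and 2612 and 3484 between the ieSC groups.

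The label numbers 1 and 2 give only 2 pairs, and the labels do not say what samples of the same number share. The deviations of names 1 from their group means correlated across genes at 0.3. Between names 1 and 2, 190 genes differed at least 2-fold in the same direction in both origins, where 20 would if independent. With 2 names per origin there is 1 difference in each, and 2 unrelated differences along a common axis would match or oppose each other by chance. The count of 20 also takes genes as varying independently. These values thus cannot show that the number marks something shared, and the main fit leaves the number out. With the number as a replicate block 8339 genes were called between the ieSC groups, against 5653 on the ieSC arrays alone without it. No paired analysis was possible by these numbers for the comparisons with MEF because the MEF name carries none. The submitters' codes set each array of a name in a low or a high series, and with that series as a fixed block 7865 genes were called for ieSC against MEF, 8203 and 7185 for MEF-derived and TTF-derived ieSCs against MEF, and 5646 between the ieSC groups. Of 5388 values of named genes under alternatives, 65 lost a call and 12 gained one, in 41 of 270 results. These genes were mostly named for a large change or a small p in the main fit, which holds the number of lost calls low. More of the losses came with the arrays of each name averaged than with any other alternative. Of 1334 values of lists, 17 lost a call and 15 gained one. Kit and Dppa5a lost theirs under 7 and 11 alternatives. The podocyte list passed for ieSC against MEF under 6 alternatives, the interferon list under 3 and the inflammatory list under 2. The cause was not tested. Without detection flags, signal over background cannot be given, and values near 5.0 and below have no measured floor.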

Other observations

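The tests of a scaling difference and of cells of both sexes were chosen only after the result was seen.

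Between names 1 and 2, 739 genes differed at least 2-fold in MEF-derived and 852 in TTF-derived ieSCs. Of these, 190 differed in the same direction in both, where 20 would if the lists were independent, and 28 in opposite directions. The count of 20 takes genes as varying independently, and 2 names per origin cannot show what the number marks. Genes of several kinds were among the 190. The matrix genes Col8a1 and Postn were lower in name 2 by 4.97 and 3.41 on the log2 scale in MEF-derived and by 3.88 and 2.45 in TTF-derived ieSCs. Lce1g, a late cornified envelope gene, was lower by 4.5 and 3.81, the carboxylesterase gene Ces2e by 4.2 and 3.73, and the matrix protease gene Mmp3 was higher by 3.63 and 1.81. These genes were picked after their values were seen, and no test was run on them.

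Of the 286 genes called in opposite directions against MEF, 196 were higher in TTF-derived and lower in MEF-derived ieSCs and 90 the reverse.

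Macrophage markers fell in ieSCs, apart from Cd14, which did not pass, and Cd53, which rose in MEF-derived ieSCs alone (10.07, against 7.75 in MEFs and 7.80 in TTF-derived ieSCs). Of 9974 other genes with MEF levels in the range of this list, 8.4% changed by -2.76 or lower, against a list median of -5.52. Most genes of such levels thus did not fall with the list. Quantile normalization gives every array the same distribution, so this share was bound to be low. The test therefore cannot decide on a scaling difference before normalization. RNA of macrophages in the MEF arrays is a candidate explanation, and it was tested on a second list of macrophage genes, written before its values were seen, of which 26 of 28 tested (92.9%) fell and 1, Clec7a, rose. The tested genes of that list appear 0 times in the fixed lists, 13 of them had mean ieSC levels above the filter level, and levels in MEFs and ieSCs were 13.8 and 3.66 for Ms4a7, 14.2 and 10.6 for Arhgdib, and 13.6 and 12.2 for Trem2, so RNA of the last 2 was measured in ieSCs too. The labels name no sort that would remove such cells, and a loss of macrophage genes from the fibroblasts themselves was not tested.

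Xist and Eif2s3y were both bright in MEFs and at the dim end in all 8 ieSC arrays. A second active X chromosome in the ieSCs is argued against: X-linked genes (59 tested) moved by 0.0037 relative to all genes, with a 95% bootstrap interval from -0.15 to 0.091. Cells of both sexes in the MEF arrays may account for the MEF values. The lower of the 2 genes lay at least 4.3 above the filter level on both MEF arrays, but this repeats the pattern itself and adds no support. Kdm5d and Uty, also Y-linked, did not pass the filter, and Uty was bright only on MEF-derived array 2b (6.62). On the TTF-derived arrays Eif2s3y stood at 3.42 to 4.01, against 10.3 in MEFs, as the female label predicts. This argues against male TTF-derived cells that still express the gene, though it rests on 1 Y-linked gene. Loss of a sex chromosome from the ieSCs stays open. So does a male origin of the TTF-derived cells with that gene lost or silenced. Neither was tested.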
